A study of Mus musculus with 6 samples.

How the data were processed

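RNA was measured by poly(A) RNA sequencing in the hypothalamus of 6 mice, 3 wild type (WT) and 3 homozygous for a Kcnb1 allele with a premature stop codon (Kcnb1-NULL). The file held 1 column of whole-number counts per library, deposited by the authors as raw counts per gene without normalisation, with 46078 Ensembl gene identifiers and their symbols. All 6 columns matched a sample label, and no other column of sample values was present. The submitters' processing notes name bcl2fastq 2.20.0.422, FastQC 0.11.8, cutadapt 2.5, STAR 2.6.1, SAMtools 1.9, Picard 2.21.1, featureCounts 1.6.4, StringTie 2.0, edgeR 3.26.5 and DESeq2 1.22.1, with the mouse genome build GRCm38, but not the order or role of each. The annotation release, the strand setting of the counting, and the library kit are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be assigned with certainty, and counts of pseudogenes and close paralogues are uncertain.

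Groups were taken from the sample titles, and libraries are named by genotype and the animal number in the title. WT libraries are 10, 11 and 173, and Kcnb1-NULL libraries are 14, 15 and 115. Per the labels' design text, each genotype had 2 animals of 1 month and 1 animal of 6 months, of either sex. No label tied an age or a sex to a library, so neither entered the model. Total counts ranged from 22767930 to 34762040 per library, and the libraries with 3-digit numbers were the deepest of their genotypes. Coordinates, biotypes, transcript GC content and transcript length came from GENCODE release M21 on GRCm38, which held 45229 (98.2%) of the identifiers, carrying 99.9% of the counts.

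Genes were kept by edgeR's filterByExpr with genotype as group, which left 17390 genes. Counts were scaled with TMM factors, and values are given as CPM (counts scaled to a fixed library total) on that scale, as mean ± SD over n = 3 libraries. The genotypes were compared with edgeR 4.0.16's quasi-likelihood test with robust estimation, in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are Kcnb1-NULL minus WT and carry their standard error (SE). For Kcnb1 an exact two-sided permutation test of log2 CPM was also run. With 3 libraries against 3 its smallest possible p is 0.1. DESeq2 1.42.0 (Wald test) and limma 3.58.1 (voom) were run as other tools. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

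Before the data were examined, 38 gene lists were fixed, for the melanocortin and leptin systems, ion channels, signalling, stress, metabolism, brain cell types, neighbouring tissues, sex, age, time of day and RNA quality. Of their 951 symbols, 5 were not found in the table. Lists with at least 3 tested members were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether the members of a list move on balance one way without comparing them with other genes, were run beside it. Member genes were also adjusted over the list alone.

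The genes named were chosen by a rule fixed together with the lists. It takes 7 genes always, namely Kcnb1, Lepr, Pomc, Agrp, Npy, Cartpt and Mc4r. Where fewer than 8 genes in a direction passed, it takes those that did, filled up to 5 with the genes of mean CPM of at least 1 with the smallest unadjusted p. It then takes up to 4 members of each list called, and 2 members of the other lists among the first 12 fixed. It also takes Xist, Y-linked genes, markers of other tissues and RNA quality genes as checks on the libraries. Genes named outside this rule are identified as such where they appear.

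Alternatives fixed together with the lists were DESeq2 size factors, upper-quartile factors, no filter, a filter of CPM of at least 1 in 3 libraries, the number series of the animal (2 or 3 digits) as a covariate, log2 CPM of Xist as a covariate, exclusion of sex-linked genes, the other tools and list tests, and each library left out in turn. Alternatives added after seeing the data were a correction of each library for a smooth trend over transcript GC content and length (mgcv 1.9.3, basis size 10, used as offsets), edgeR's newer quasi-likelihood setting in place of the package default, the 4 libraries with 2-digit numbers alone, the nuclear-retained list without Xist, and an adjusted p threshold of 0.1.

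The procedure was tested on simulated counts drawn from the means and library sizes of these 17390 genes, with 200 genes changed. For this comparison edgeR recovered 2.99% of the genes changed 1.5-fold, 64.2% of those changed 2-fold and 90.9% of those changed 4-fold, with 5.41% false among its calls. DESeq2 recovered 16.4%, 71.6% and 95.5% in the same order, with 18.1% false, and limma-voom 1.49%, 58.2% and 92.4%, with 5.61% false. With no change simulated camera called 0 lists at the preset correlation. It called 2 lists when 1 list had been changed 1.5-fold, among them the changed list. Each gene was drawn independently of the others. The simulation therefore does not check camera's calls where the genes of a list move together. A simulated GC trend of 0.0502 log2 units per percent GC was 0.000882 after the correction.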

Results

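The hypothalamic transcriptome was profiled in 3 WT C57BL/6J mice and 3 mice homozygous for Kcnb1-NULL, an allele with a nonsense mutation in the exon for the S4 segment of KCNB1 (Kv2.1), the pore-forming subunit of a delayed-rectifier potassium channel. Total counts were 26004657, 25587108 and 34762040 in WT libraries 10, 11 and 173. They were 22767930, 25601296 and 34155059 in Kcnb1-NULL libraries 14, 15 and 115. After filtering, 17390 genes were compared, and the biological coefficient of variation was 21.9%. Pairwise correlations of log2 CPM lay between 0.942 and 0.989, and no library duplicated another. The first principal component held 55.1% of the variance and placed the WT libraries at -58.0, -31.3 and -11.2. The Kcnb1-NULL libraries were at -2.43 (library 14), 37.9 (library 15) and 65.1 (library 115). The second component held 23.9% and did not follow genotype. On it WT 10, WT 173 and Kcnb1-NULL 115 were at 13.7, 44.1 and 16.1. WT 11, Kcnb1-NULL 14 and Kcnb1-NULL 15 were at -23.3, -35.3 and -15.3.

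The first comparison asked whether the message of the targeted gene differed between genotypes. Kcnb1 (ENSMUSG00000050556, chromosome 2, 167095969 to 167190155, minus strand, GRCm38) averaged 30.5 ± 7.22 CPM in WT and 29.0 ± 6.34 CPM in Kcnb1-NULL libraries (SD, n = 3 each), from 588 to 1308 counts per library. The log2 fold change was -0.07 (SE 0.22, 95% interval -0.554 to 0.412) with an edgeR adjusted p of 0.83, and the exact permutation test gave p = 0.8. The difference was within the spread between replicates. A count per gene does not see a single stop codon, so this level does not check the genotype labels. After the correction for GC content and length the log2 fold change was -0.47 (adjusted p 0.0642). It was above 0 without WT 173 (0.13), without Kcnb1-NULL 14 (0.02) or without Kcnb1-NULL 15 (0.01).

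The second comparison concerned Lepr, which encodes the leptin receptor, and the melanocortin genes that act downstream of leptin. Lepr (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352) averaged 2.36 ± 0.435 CPM in WT and 6.59 ± 3.25 CPM in Kcnb1-NULL libraries (SD, n = 3 each), a log2 fold change of 1.48 (SE 0.38). All 3 Kcnb1-NULL libraries lay above all 3 WT libraries, but library 14 was at 3.09 CPM against 7.15 and 9.53 in libraries 15 and 115, and the highest WT library was at 2.69. The edgeR adjusted p was 0.0506, and Lepr therefore did not pass. It passed under 7 of 18 alternatives, among them the number series of the animal as a covariate (log2 fold change 1.44, adjusted p 0.0107), no filter (0.00933) and DESeq2 (0.00271), while limma-voom gave 0.065 and Xist as a covariate 0.0672. The adjusted p ranged from 0.00115 (without Kcnb1-NULL 14, log2 fold change 1.81) to 0.21 over the alternatives, and the log2 fold change was 0.97 after the correction for GC content and length (adjusted p 0.084). The neighbouring gene Leprot (ENSMUSG00000035212, chromosome 4, 101647718 to 101659364), named outside the rule, does not overlap Lepr in the annotation used. Leprot had a log2 fold change of -0.65 (SE 0.19) with 47.3 ± 10.6 CPM in WT and 30.1 ± 2.39 CPM in Kcnb1-NULL libraries. Its adjusted p was 0.055. The annotation behind the counts is not given, so how it assigned reads from upstream exons that the 2 genes have been described to share is unknown, and both counts are uncertain.

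Pomc, the precursor of the melanocortin peptides, averaged 558 ± 858 CPM in WT and 773 ± 771 CPM in Kcnb1-NULL libraries (log2 fold change 0.47, SE 1.96, adjusted p 0.882). Its spread within each genotype was larger than the difference, and the library values ran from 22 in WT 173 to 1589 in Kcnb1-NULL 14, the library in which pituitary genes took 1.63% of the counts. The log2 fold change ran from -0.61 without Kcnb1-NULL 14 to 3.61 without WT 11, and it was also negative without WT 10 (-0.03) or WT 173 (-0.10). The antagonist Agrp averaged 5.15 ± 1.27 CPM in WT and 5.74 ± 1.75 CPM in Kcnb1-NULL libraries. Npy averaged 32.6 ± 8.82 and 25.5 ± 0.557 CPM, Cartpt 131 ± 49.5 and 109 ± 37.8 CPM, and the melanocortin receptor gene Mc4r 4.65 ± 1.15 and 4.97 ± 0.814 CPM in the same order. None of these 5 genes passed (adjusted p 0.227 to 0.882), and each difference was smaller than the larger SD of its groups. The log2 fold change of Agrp turned negative without Kcnb1-NULL 115 (-0.11) or WT 11 (-0.02) and that of Mc4r without WT 11 (-0.10).

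**Figure D1:**
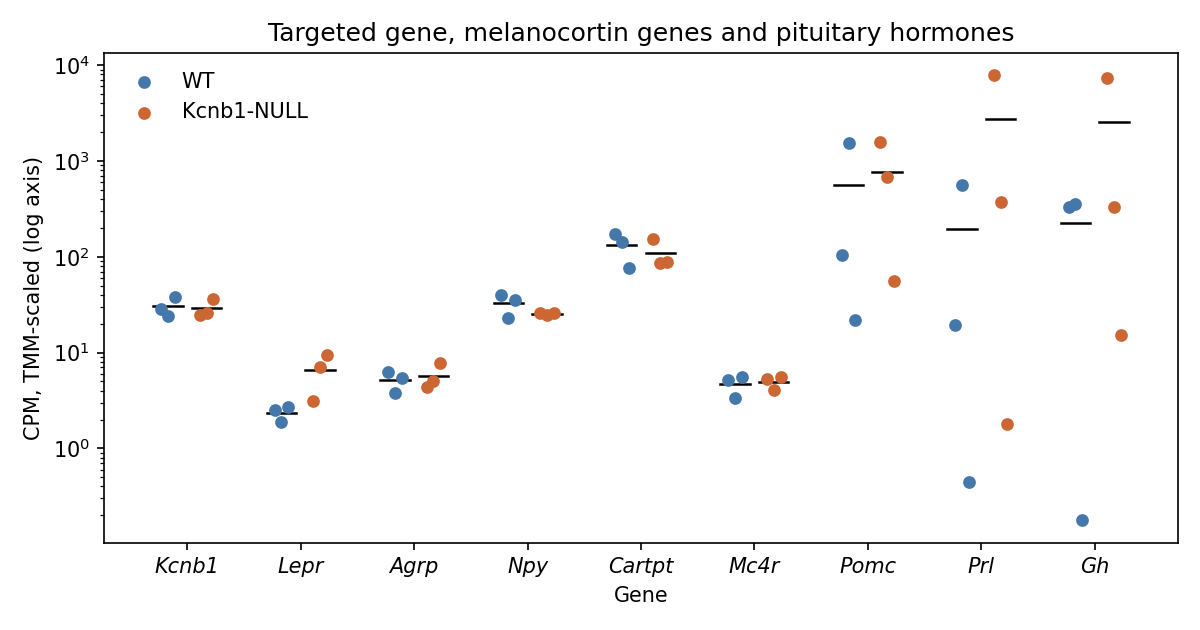
CPM (log axis) of the targeted gene, 5 melanocortin genes, Lepr and the pituitary hormone genes Prl and Gh in each library, with bars for the mean of each genotype (n = 3). The 3 Kcnb1-NULL values of Lepr lie above the 3 WT values, while Pomc, Prl and Gh spread over more than a factor of 10 within each genotype.

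The third comparison covered all genes. Named here are the 5 genes with the smallest p in each direction, in all of which the 3 Kcnb1-NULL values lay on one side of the 3 WT values. Chance alone separates 10% of genes in this way with 3 libraries against 3. Higher values were seen for Prlr, the prolactin receptor (25.2 ± 1.54 CPM in WT, 49.2 ± 5.31 CPM in Kcnb1-NULL, log2 fold change 0.96, SE 0.15), and for Gabrq, the theta subunit of the GABA-A receptor (51.7 ± 6.13 and 107 ± 16.6 CPM, 1.05, SE 0.16). Ak7, an adenylate kinase of motile cilia, was at 4.00 ± 0.583 and 11.6 ± 3.12 CPM (1.53, SE 0.24). The noncoding RP23-441I24.5 (1.98, SE 0.31) and the processed pseudogene Gm6548 (1.70, SE 0.26), whose counts are uncertain because a parent gene may share its reads, completed the 5 higher genes. Lower values were seen for Dlgap3, a postsynaptic scaffold protein of excitatory synapses (221 ± 7.94 CPM in WT, 105 ± 8.48 CPM in Kcnb1-NULL, -1.07, SE 0.13), and Camk2n1, an inhibitor of CaM kinase II (1282 ± 123 and 608 ± 88.3 CPM, -1.08, SE 0.16). The transcription factor Scrt2 (20.2 ± 1.97 and 9.69 ± 0.289 CPM, -1.06, SE 0.16), Nrn1 (117 ± 8.88 and 61.3 ± 6.48 CPM, -0.94, SE 0.14) and Lingo1 (136 ± 2.42 and 74.2 ± 7.59 CPM, -0.88, SE 0.13) were the other 3.

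None of these 10 genes passed, and neither did any other gene. The edgeR test gave 0 genes at an adjusted p under 0.05, and 1241 genes shared its smallest adjusted p of 0.0506. At an unadjusted p under 0.05 there were 6480 genes, 3436 higher and 3044 lower. DESeq2 called 4023 genes at an adjusted p under 0.05 (2216 higher, 1807 lower), of which 4018 were among those 6480, and limma-voom called 0, with 6551 at an unadjusted p under 0.05. In the simulated data DESeq2 had 18.1% false calls against 5.41% for edgeR. That simulation changed 200 genes, and the share of false calls can differ where more genes change. The edgeR count became 5657 without Kcnb1-NULL 14, the Kcnb1-NULL library nearest to the WT libraries on the first component, and it became 5506 with the number series of the animal as a covariate. The count at an unadjusted p under 0.05 was 3662 without WT 10, 3898 without Kcnb1-NULL 15 and 4016 without Kcnb1-NULL 115.

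Fold changes followed the base composition of transcripts. Across genes, which are not independent replicates, Spearman's rho of the log2 fold change was -0.486 with transcript GC content and 0.332 with transcript length. The median log2 fold change was 0.37 among the 3464 genes of lowest GC content (28.7% to 43.8%) and -0.38 among the 3464 of highest (55.5% to 84.2%). By library, the median deviation of the genes of lowest GC content was -0.41 in WT 10, -0.09 in WT 11 and -0.05 in WT 173, against 0.03, 0.22 and 0.31 in Kcnb1-NULL 14, 15 and 115. After the correction for GC content and length 5745 genes were at an unadjusted p under 0.05, with 2426 (42.2%) higher and 3319 lower, against 53.0% higher before it. The corrected log2 fold change of Prlr was 0.26 (SE 0.18), that of Gabrq 0.68 (SE 0.10) and that of Ak7 1.42 (SE 0.22). For Dlgap3 it was -0.73 (SE 0.11) and for Camk2n1 -1.02 (SE 0.14).

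**Figure D2:**
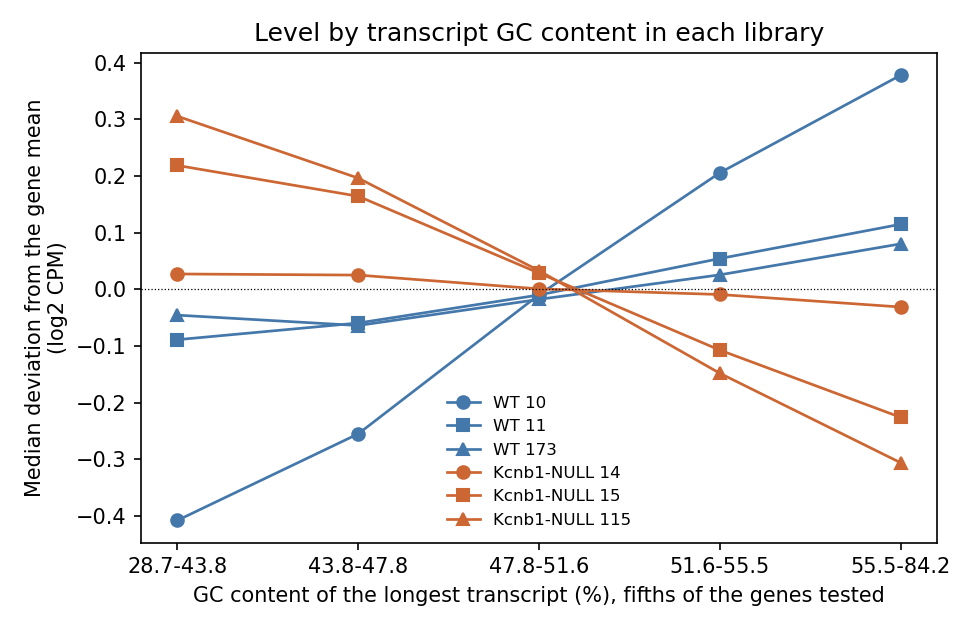
Median deviation of genes from their mean over the 6 libraries (log2 CPM), by transcript GC content (percent, 5 classes of equal size), 1 line per library. The WT lines climb from left to right, apart from a small dip of WT 173 in the second class, and the Kcnb1-NULL lines descend. WT 10 and Kcnb1-NULL 115 are the extremes and Kcnb1-NULL 14 is nearly flat.

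The fourth comparison set the gene lists fixed beforehand against all other genes. By their medians, nuclear respiration genes and genes for ribosomes, sterol synthesis, glia and forebrain regions outside the hypothalamus were lower in Kcnb1-NULL libraries. Long RNAs kept in the nucleus were higher. These groups were called only by a test that assumes little correlation between genes. With camera at the preset correlation 12 of 38 lists passed, 11 lower and 1 higher. None of these calls held with an estimated correlation (adjusted p = 0.745 for each of the 12) or with fry (adjusted p 0.299 to 0.555). No member gene of any list passed over all genes tested in edgeR, whereas DESeq2 called members of many lists, among them 46 lower and 1 higher in oxidative phosphorylation and 10 lower and 1 higher in the cortex list. The other 9 ways to split the 6 libraries into groups of 3 gave from 11 to 29 lists at the preset correlation, so 12 calls were no more than such splits gave. Those splits hold the genotypes unequally on their sides and so keep a part of the genotype difference.

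Nuclear genes of oxidative phosphorylation had a median log2 fold change of -0.60, with 65 of 69 tested members negative (camera adjusted p 9.2e-15). Adjusted over the list alone 54 were lower and 1 higher. These genes took 1.37% to 1.56% of the counts of the WT libraries and 0.934% to 1.29% of those of the Kcnb1-NULL libraries, without overlap. Cox6a1, a subunit of cytochrome c oxidase, averaged 404 ± 50.5 CPM in WT and 220 ± 43.5 CPM in Kcnb1-NULL libraries, Cox8a 467 ± 54.9 and 259 ± 56.7 CPM, and Atp5j, a subunit of ATP synthase, 249 ± 19.8 and 156 ± 16.3 CPM. The 8 tested genes encoded by mitochondrial DNA had no shared direction between the genotypes (median -0.03, mean 0.04, camera adjusted p 0.952). Camera's estimated correlation between them was 0.476. Their median was -0.20 after the correction for GC content and length (adjusted p 0.714), where camera's direction turned downward. Of these 8 genes, 2 were higher and 1 was lower adjusted over the list alone. Cytosolic ribosomal protein genes had a median of -0.44, with 68 of 75 negative (adjusted p 6.4e-07) and 0 past the threshold adjusted over the list alone. That median was -0.70 without Kcnb1-NULL 14 and -0.27 without Kcnb1-NULL 115. Ribosomal genes took 1.84%, 1.84% and 1.38% of the counts of WT 10, 11 and 173. They took 1.83%, 1.31% and 1.12% of those of Kcnb1-NULL 14, 15 and 115, so the genotypes overlapped. Rpl27 averaged 111 ± 11.0 CPM in WT and 71.9 ± 14.4 CPM in Kcnb1-NULL libraries, and Rps14 346 ± 31.0 and 234 ± 59.3 CPM. Both groups kept their camera calls after the correction for GC content and length, with medians of -0.49 and -0.29.

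Genes of cholesterol biosynthesis had a median of -0.41, with 20 of 23 negative (adjusted p 3.9e-04) and 10 lower adjusted over the list alone, and the median was -0.43 after the correction for GC content and length (adjusted p 5.5e-06). Mvd and Mvk, enzymes of the mevalonate pathway, averaged 37.6 ± 5.49 and 39.5 ± 6.09 CPM in WT against 20.7 ± 3.63 and 24.1 ± 2.23 CPM in Kcnb1-NULL libraries. Dhcr24, which acts late in the pathway, averaged 182 ± 35.0 and 114 ± 4.25 CPM. All 9 nuclear-retained long RNAs had positive log2 fold changes (median 0.61, adjusted p 0.0137), 2 of them higher adjusted over the list alone. The list includes Xist, which was high in some libraries of each genotype and near 0 in the others, and without it the other 8 had a median of 0.61 (adjusted p 0.0131). Snhg11 averaged 2031 ± 297 CPM in WT and 3081 ± 432 CPM in Kcnb1-NULL libraries, and the imprinted Meg3 4377 ± 1444 and 7865 ± 2956 CPM. These RNAs without Xist took 0.562% to 0.974% of the counts of the WT libraries and 0.998% to 1.82% of those of the Kcnb1-NULL libraries. After the correction for GC content and length the call ended, with a median of 0.18 (adjusted p 0.173, quartiles of the 9 members -0.139 and 0.522, before it 0.511 and 0.846), as the mean z-score of the members fell from 1.96 to 0.868.

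Markers of glia had negative medians, but in each of these lists the shares of counts overlapped between the genotypes. Myelin genes took 0.877% to 1.68% of the counts of the WT libraries and 0.649% to 1.51% of those of the Kcnb1-NULL libraries. Astrocyte genes took 0.747% to 0.830% and 0.671% to 0.773% in the same order. For microglia and macrophages the median was -0.38, with 14 of 19 negative (adjusted p 0.0287), and adjusted over the list alone 8 were lower and 1 higher. Without Kcnb1-NULL 115 the median was -0.25 (adjusted p 0.0138), and after the correction for GC content and length it was -0.29 (adjusted p 0.0352). Tmem119 averaged 30.4 ± 5.12 CPM in WT and 18.5 ± 1.52 CPM in Kcnb1-NULL libraries, and Trem2 17.8 ± 4.21 and 10.1 ± 1.71 CPM. Oligodendrocyte precursors and new oligodendrocytes had a median of -0.46, with 13 of 17 negative (adjusted p 0.0323). Adjusted over the list alone 5 were lower, including Sox10 (104 ± 16.5 and 55.3 ± 10.6 CPM), and 2 higher, including Vcan (11.1 ± 2.18 and 25.5 ± 10.4 CPM). Myelin and mature oligodendrocyte genes had a median of -0.45, with 16 of 20 negative (adjusted p 0.0443). Astrocyte markers had a median of -0.37, with 14 of 17 negative (adjusted p 0.0469). In both, 0 passed adjusted over the list alone, and Cnp averaged 1017 ± 367 and 522 ± 134 CPM and Aldoc 1593 ± 178 and 1185 ± 156 CPM.

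The glial calls ended under several settings, in part with medians as large as before. The myelin call ended without WT 10 (median -0.35, camera adjusted p 0.123), WT 173 (-0.48, 0.0864) or Kcnb1-NULL 14 (-0.29, 0.617), while without Kcnb1-NULL 15 the myelin median was -0.80 (4.3e-05). The precursor call ended without WT 173 (-0.40, 0.122) or Kcnb1-NULL 14 (-0.33, 0.355). The astrocyte call ended without WT 10 (median -0.22, adjusted p 0.112), WT 11 (-0.38, 0.0545), Kcnb1-NULL 14 (-0.41, 0.0729) or Kcnb1-NULL 15 (-0.28, 0.0683). After the correction for GC content and length the myelin median was -0.59 (quartiles of the members -0.722 and -0.155, before it -0.876 and -0.132) with an adjusted p of 0.06. The precursor median was -0.35 (quartiles -0.482 and -0.16, before it -0.539 and -0.276) with an adjusted p of 0.0797. In camera's z-scores the myelin members went from a mean of -1.06 to -1.18 and the precursor members from -1.21 to -1.15, while the mean of the other genes went from 0.0363 to between -0.188 and -0.187, so these calls ended mainly because the other genes moved downward. The astrocyte list kept its call with a corrected median of -0.29 (adjusted p 0.0284). The 2-digit libraries alone did not give the precursor call (median -0.39, adjusted p 0.0853). The filter of CPM of at least 1 in 3 libraries ended the calls of these 3 lists and of the microglial, thalamic and immediate early gene lists (medians -0.449 to -0.237, adjusted p 0.0513 to 0.0713). Xist as a covariate ended those of the same lists except the thalamic one (adjusted p 0.056 to 0.151), with medians of -0.32 for myelin, -0.31 for precursors, -0.33 for astrocytes, -0.48 for microglia and -0.19 for immediate early genes.

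Markers of forebrain regions outside the hypothalamus had negative medians too. Those of the striatum had a median of -0.82, with 15 of 16 negative (adjusted p 7.6e-04) and 3 lower adjusted over the list alone. Without WT 173 the median was -0.54 (adjusted p 0.0208), and after the correction for GC content and length it was -0.69 (adjusted p 0.00151). These genes took 0.1106% of the counts of WT 173 against 0.0462% to 0.0671% in the other 5 libraries, among which WT 11 (0.0555%) lay below Kcnb1-NULL 14 (0.0572%). Ppp1r1b (DARPP-32) averaged 88.6 ± 60.0 CPM in WT and 23.5 ± 8.93 CPM in Kcnb1-NULL libraries, and Syndig1l 41.6 ± 3.83 and 19.7 ± 3.80 CPM. Those of the cortex, hippocampus and amygdala had a median of -0.76, with 17 of 20 negative (adjusted p 5.3e-04), 10 lower and 1 higher adjusted over the list alone. Without WT 173 that median was -0.40 (adjusted p 0.00766), and the corrected median was -0.86 (adjusted p 3.9e-04). These genes took 0.139%, 0.1179% and 0.1927% of the counts of WT 10, 11 and 173. They took 0.0939% to 0.0983% of those of the Kcnb1-NULL libraries, so the genotypes did not overlap, with WT 173 the highest. Camk2a averaged 724 ± 172 CPM in WT and 378 ± 25.6 CPM in Kcnb1-NULL libraries, and Slc30a3, the synaptic zinc transporter, 14.7 ± 6.05 and 4.73 ± 0.737 CPM. Rasgrf2 went the other way (106 ± 19.3 and 191 ± 28.7 CPM). Thalamic and habenular markers had a median of -0.26, with 18 of 21 negative (adjusted p 0.0287) and 1 lower adjusted over the list alone. Tcf7l2 averaged 107 ± 24.6 and 47.3 ± 18.4 CPM. That call ended without WT 11 (median -0.18, adjusted p 0.155) or Kcnb1-NULL 14 (median -0.39, adjusted p 0.127), and its median was -0.41 without WT 10 and -0.47 without Kcnb1-NULL 15. The call stayed after the correction for GC content and length, with a median of -0.50 (adjusted p 0.00518).

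**Figure D3:**
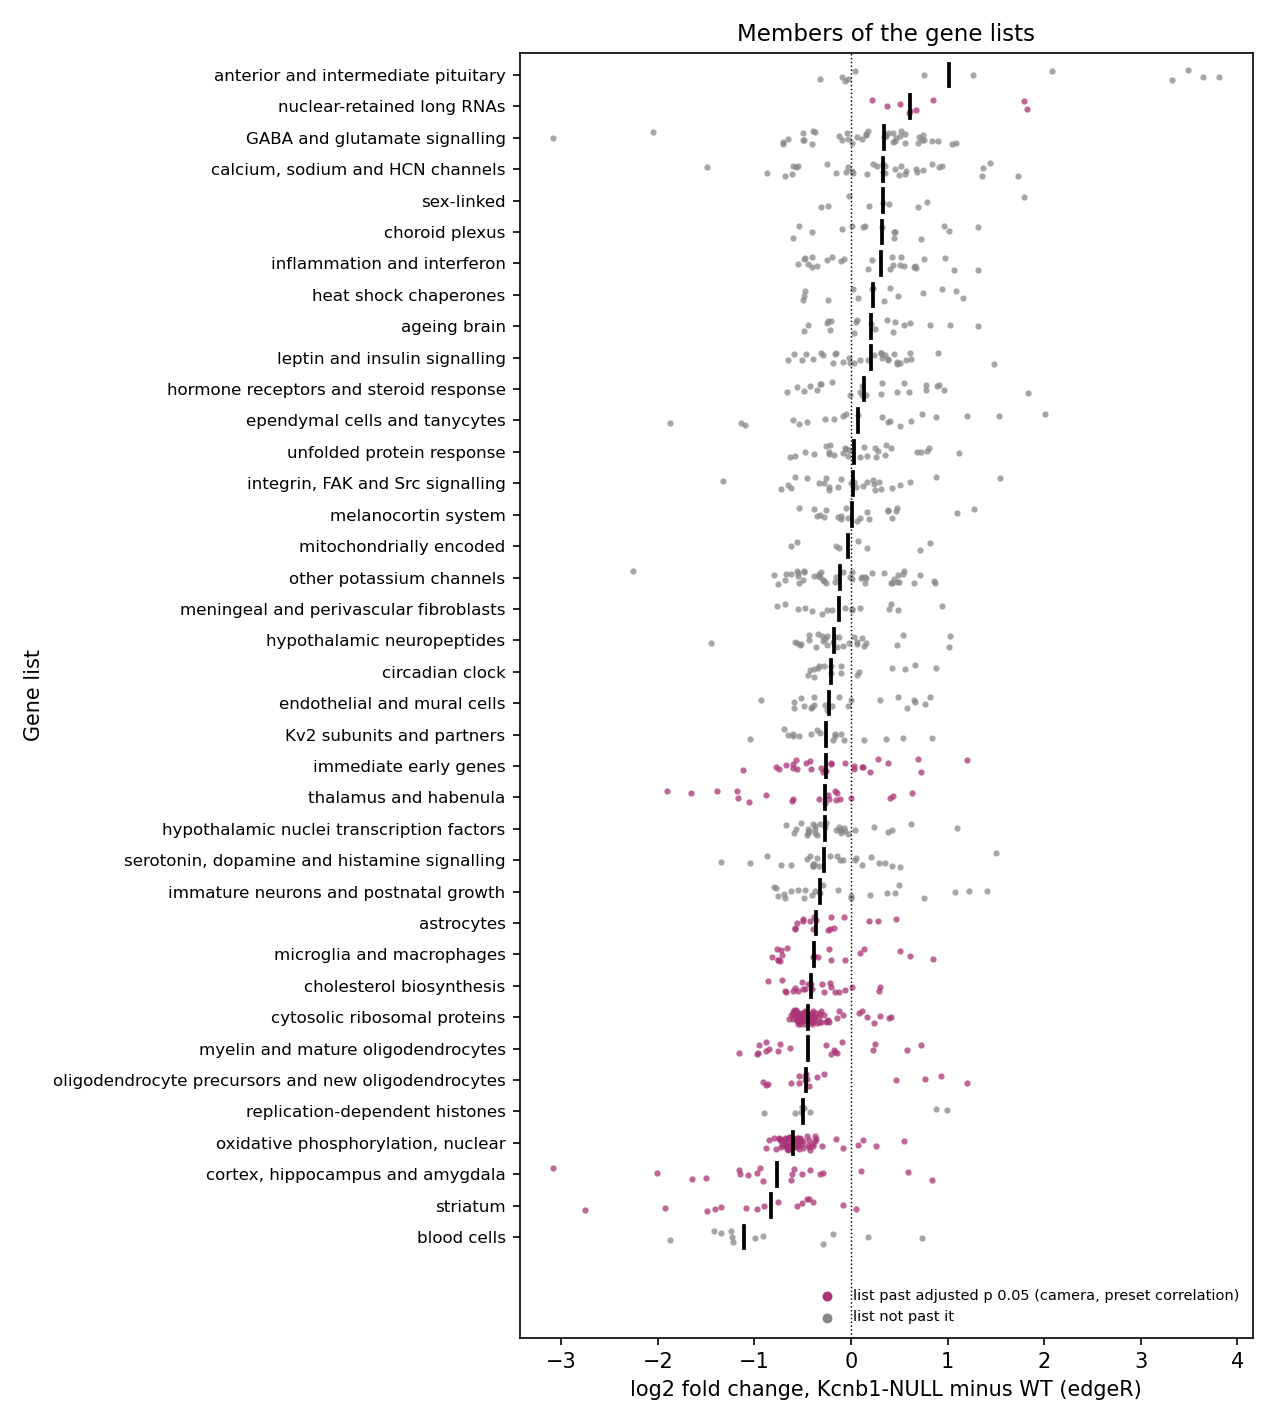
Log2 fold change (Kcnb1-NULL minus WT, edgeR) of each tested member of the 38 lists, sorted by the median (black bar). Coloured lists passed camera at the preset correlation. Oxidative phosphorylation genes lie almost wholly below 0 (65 of 69), while the melanocortin list is centred near 0 (median 0.02).

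Lists for the biology named by the study did not pass. The melanocortin system had a median of 0.02, with 11 of 22 members positive (adjusted p 0.424). Its median was -0.13 without WT 173 or without Kcnb1-NULL 14 and just below 0 (-0.0025) without Kcnb1-NULL 115, and 0.04 after the correction for GC content and length. Adjusted over the list alone 2 were higher, namely Pcsk1, the convertase that cleaves the Pomc precursor (18.4 ± 3.02 CPM in WT, 44.3 ± 12.0 CPM in Kcnb1-NULL), and Sim1, a transcription factor of the paraventricular nucleus (7.02 ± 0.966 and 15.0 ± 3.18 CPM). Leptin and insulin signalling genes had a median of 0.21 (adjusted p 0.549) and 0 of 32 passed adjusted over the list alone, Jak2 being at 21.5 ± 5.83 and 40.2 ± 9.34 CPM. That median was -0.05 after the correction for GC content and length, 0.13 without WT 173 and 0.01 without Kcnb1-NULL 115. Hypothalamic neuropeptides had a median of -0.17 (adjusted p 0.346), with 1 higher and 1 lower adjusted over the list alone. Those were Vip (6.34 ± 1.23 and 12.8 ± 0.305 CPM) and Cck (88.8 ± 11.5 and 32.6 ± 14.2 CPM). The list passed without WT 173 (median -0.31, adjusted p 0.0396), and its median was -0.03 without WT 10, -0.43 without Kcnb1-NULL 14 and -0.06 without Kcnb1-NULL 115. It was -0.01 after the correction for GC content and length (adjusted p 0.866), where camera's direction turned upward.

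Kv2 subunits and partners had a median of -0.25, with 14 of 18 negative (adjusted p 0.117) and 0 past the threshold adjusted over the list alone. Vapa, a protein of the contacts between endoplasmic reticulum and plasma membrane that Kv2 channels organise, averaged 250 ± 22 CPM in WT and 172 ± 31.3 CPM in Kcnb1-NULL libraries. Amigo3 averaged 2.16 ± 0.330 and 3.86 ± 0.330 CPM. The list passed after the correction for GC content and length (median -0.37, adjusted p 0.0352), without WT 11 (adjusted p 0.041) and without Kcnb1-NULL 115 (0.0498). Other potassium channel genes had a median of -0.11 (adjusted p 0.221), with 7 of 46 lower adjusted over the list alone, among them Kcnab2 (306 ± 29.3 and 176 ± 16.7 CPM). They passed after the correction (median -0.25, adjusted p 0.0284), and their median was -0.04 without WT 173 and near 0 (-0.00426) without Kcnb1-NULL 14. Calcium, sodium and HCN channel genes went both ways, with a median of 0.33 (adjusted p 0.221). Adjusted over the list alone 9 of 35 were higher, including Scn9a (20.2 ± 3.17 and 52.2 ± 17.7 CPM), and 7 lower, including Scn1b (351 ± 49.8 and 193 ± 28.8 CPM). The list passed without WT 173 (adjusted p 0.0398) or without Kcnb1-NULL 14 (0.0282), and its median was 0.20 without WT 10 and 0.01 after the correction for GC content and length (adjusted p 0.866).

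GABA and glutamate signalling genes likewise divided, with 13 higher and 10 lower of 43 adjusted over the list alone and a median of 0.34 (adjusted p 0.247), or -0.08 after the correction for GC content and length. The median was 0.20 without WT 10 and 0.19 without Kcnb1-NULL 115. Grm2, a presynaptic glutamate receptor, averaged 56.4 ± 4.01 CPM in WT and 35.8 ± 1.75 CPM in Kcnb1-NULL libraries. Immediate early genes passed with a median of -0.26, 18 of 28 being negative (adjusted p 0.0287), but 0 passed adjusted over the list alone and the members differed. Nptx2 averaged 55.5 ± 7.15 and 37.5 ± 0.278 CPM and Vgf 660 ± 149 and 445 ± 8.92 CPM, while Npas4 averaged 6.39 ± 1.67 and 14.8 ± 7.65 CPM. The median was -0.17 without WT 10 and -0.58 without Kcnb1-NULL 14. That call ended without Kcnb1-NULL 15 (median -0.05, adjusted p 0.406) and after the correction for GC content and length (median -0.09, adjusted p 0.276, quartiles of the members -0.399 and 0.275, before it -0.564 and 0.116). The mean z-score of the members went from -1.02 to -0.702 and that of the other genes from 0.0368 to -0.188.

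Integrin, FAK and Src signalling genes had a median of 0.02, a mean of -0.01 and an adjusted p of 0.611, and the camera direction was downward. The median was -0.19 after the correction for GC content and length, -0.07 without WT 11, -0.02 without Kcnb1-NULL 15 and -0.06 without Kcnb1-NULL 115, and camera turned upward without Kcnb1-NULL 14 (median 0.10). Of 28 members 3 were lower adjusted over the list alone. Src averaged 154 ± 12.4 CPM in WT and 100 ± 12.1 CPM in Kcnb1-NULL libraries, and its substrate Bcar1 85.5 ± 12.5 and 54.4 ± 5.74 CPM. The unfolded protein response list had a median of 0.04 (adjusted p 0.553), from -0.05 (without Kcnb1-NULL 14) to 0.11 (without WT 11) over the left-out libraries and 0.11 after the correction for GC content and length, with 6 of 28 higher and 2 lower adjusted over the list alone, the chaperone Hsp90b1 being at 174 ± 20.9 and 378 ± 124 CPM. Inflammation and interferon genes had a median of 0.31 (adjusted p 0.285), 0.15 without WT 10, 0.56 without WT 11 and 0.13 after the correction for GC content and length (adjusted p 0.0797), and 2 of 26, Ifit1 (2.38 ± 0.332 and 4.66 ± 0.373 CPM) and Ikbkb (19.2 ± 2.71 and 40.3 ± 14.2 CPM), were higher adjusted over the list alone.

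Libraries also differed in features that genotype did not account for. Xist, transcribed from the inactive X chromosome, was at 304 CPM in WT 11 and at 467 and 586 CPM in Kcnb1-NULL 14 and 15, and under 1 CPM in the other 3 libraries. The Y-linked Ddx3y was at 60.4 CPM in WT 10, 78.6 CPM in WT 173 and 112 CPM in Kcnb1-NULL 115, and under 1 CPM in the other 3. By both genes WT 11 and Kcnb1-NULL 14 and 15 look female and the other 3 male, so the sexes were not balanced between the genotypes. The second principal component split the libraries in the same way. Anterior and intermediate pituitary genes took 1.63% of the counts of Kcnb1-NULL 14, against 0.0324% to 0.137% in the other 5 libraries. In Kcnb1-NULL 14 the prolactin gene Prl was at 7852 CPM and the growth hormone gene Gh at 7284 CPM. The pituitary list had a median of 1.01 (adjusted p 0.418), or 1.52 after the correction for GC content and length (adjusted p 0.06), with 0 of 12 past the threshold adjusted over the list alone. The sex-linked list had a median of 0.33 (adjusted p 0.418), or 0.08 after it, also with 0 of 9.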

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

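The correction for GC content and length, the newer edgeR setting, the 2-digit libraries alone, the nuclear-retained list without Xist and the adjusted p threshold of 0.1 were chosen only after the results were seen. No paired analysis was possible because the genotypes share no animal numbers. The count of genes at an adjusted p under 0.05 in edgeR, 0, sat just short of the threshold. It was also 0 with DESeq2 size factors, the Xist covariate, the sex-linked genes left out, the GC correction and limma-voom. It was 1608 with upper-quartile factors (1157 higher, 451 lower), 2872 with no filter, 1943 with CPM of at least 1 in 3 libraries and 5506 with the number series as covariate. It was 4023 with DESeq2, 1347 with the newer setting, 5083 at the threshold of 0.1 (2822 higher, 2261 lower) and 1 with the 2-digit libraries alone. That gene, Vdac3-ps1, a pseudogene of uncertain count outside the naming rule, had a log2 fold change of -2.49 there and -1.23 in all 6 libraries. Leaving out each library gave 0 to 5657 genes, 5657 being without Kcnb1-NULL 14, and 3662 to 7954 genes at an unadjusted p under 0.05. Lists called numbered 6 with CPM of at least 1 in 3 libraries, 0 with an estimated correlation, 0 with fry and 10 to 14 over the left-out libraries.

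The Kcnb1 log2 fold change ran from -0.26 to 0.13 over the left-out libraries and was 0.11 with the Xist covariate. Pomc was at -0.56 with that covariate and ran from -0.61 to 3.61. Agrp ran from -0.11 to 0.32 and was -0.0772 in the 2-digit libraries, and Mc4r ran from -0.10 to 0.23 and was -0.15 after the GC correction. The lists called and the first 12 fixed were recomputed under each list setting, and the remaining ones are given only after the GC correction. Among the former, the direction that camera gives turned for integrin signalling with the Xist covariate (median 0.083) and, after the GC correction, for leptin and insulin (-0.0467), neuropeptides (-0.0123) and GABA and glutamate (-0.0807), and also for integrin signalling without Kcnb1-NULL 14 and the melanocortin list without WT 173. Among the remaining ones it turned after the GC correction for mitochondrially encoded genes (-0.201), hypothalamic nuclei transcription factors (-0.139) and meningeal fibroblasts (-0.0407), and the median changed sign for hormone receptors (-0.000979) and ependymal genes (-0.0145). Among the former, medians changed sign for leptin and insulin and for GABA and glutamate after the GC correction (values above), and for integrin signalling after the GC correction (-0.191), with no filter (-0.0162), in the 2-digit libraries (-0.0178) and over the left-out libraries (-0.0703 to 0.103). So did the melanocortin list with no filter (-0.0547), with the Xist covariate (-0.0855), in the 2-digit libraries (-0.0335) and over the left-out libraries (-0.135 to 0.0859), and the unfolded protein response with the Xist covariate (-0.0219) and over the left-out libraries (-0.048 to 0.108). The cause of these changes was not tested. Apart from left-out libraries, 615 values of the single genes named other than Kcnb1 stayed on the same side of the threshold, 366 came past it and 3 changed sign. In the simulation, with 200 genes changed, edgeR recovered 2.99% of the genes changed 1.5-fold against 90.9% at 4-fold. Recovery at an adjusted p depends on how many genes change, so these shares need not hold where more genes differ.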

Other observations

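The gene families, the correction for GC content and length as an alternative, the test of the gene count with Xist as covariate, both tests on Pomc, the reading of the TEC share that lay near its bound, and the split counts for genes past an adjusted p and for lists were chosen only after the results were seen. So were the TEC shares by number series and the lncRNA and sense intronic shares. The genes named in the first 3 paragraphs were chosen after their values were seen, except Sim1, Prlr, Ak7 and marker or RNA quality genes, which the naming rule covers. None of them passed an adjusted p of 0.05 over all genes tested in edgeR.

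The families Dnah and Cfap of motile cilia, Cep of centrosomes and Zfp of zinc finger proteins were higher in the Kcnb1-NULL libraries, while Mrpl and Mrps of mitochondrial ribosomes and Psmb of the proteasome were lower, by a test that assumes little correlation between genes. The tested genes were grouped by the stem of their symbol into 182 families of at least 10 members, of which 54 passed camera at the preset correlation, 28 higher and 26 lower. With an estimated correlation 0 of the 182 passed (smallest adjusted p 0.685). After the correction for GC content and length 47 of these families passed again in the same direction. For the Dnah family of axonemal dynein heavy chains, 12 of 15 genes were higher and 0 lower at an unadjusted p under 0.05 (median log2 fold change 1.39, corrected 0.71). Dnah12 averaged 1.33 ± 0.219 CPM in WT and 5.36 ± 2.66 CPM in Kcnb1-NULL libraries (n = 3 each), and Dnah1 23.4 ± 4.68 and 43.7 ± 7.07 CPM. The Cfap family of cilia and flagella proteins had 13 of 18 higher (median 1.02, corrected 0.62), with Cfap46 at 9.56 ± 1.36 and 26.3 ± 9.89 CPM, and the Cep family of centrosomal proteins 24 of 35 higher and 1 lower (0.79, corrected 0.48). Of 351 Zfp genes 190 were higher and 28 lower (median 0.62, corrected 0.29). Foxj1, the transcription factor of motile cilia in the ependymal list, was at 36.6 ± 8.10 and 26.7 ± 3.08 CPM. In the other direction lay Mrpl (median -0.38, corrected -0.30, 21 of 48 lower, 0 higher), Mrps (-0.43, corrected -0.30, 15 of 29 lower, 0 higher) and Psmb (-0.52, corrected -0.32, 8 of 10 lower, 0 higher). The other proteasome family tested, Psmd, did not pass (median -0.13, corrected -0.12, 4 of 14 lower, 1 higher, adjusted p 0.448).

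In this and the next paragraph, a corrected value is the list's median after the correction for GC content and length. Hormone receptor genes had a median of 0.14 (camera adjusted p 0.247, corrected -0.000979, so that its sign turned), and adjusted over the list alone 5 of 24 were higher and 1 lower. The oestrogen receptor gene Esr1 averaged 13.6 ± 0.532 CPM in WT and 25.2 ± 6.81 CPM in Kcnb1-NULL libraries, and the growth hormone receptor gene Ghr 16.5 ± 1.43 and 25.1 ± 2.51 CPM. Thrb averaged 16 ± 3.47 and 27.5 ± 4.43 CPM while Thra, which encodes the other thyroid hormone receptor, averaged 815 ± 107 and 552 ± 73.4 CPM. Circadian clock genes had a median of -0.20 (adjusted p 0.592, corrected -0.10), with 3 of 17 higher adjusted over the list alone, among them Per3 (35.8 ± 3.29 and 56.8 ± 2.84 CPM). Heat shock chaperones had a median of 0.23 (0.296, corrected 0.29), with 3 of 15 higher, among them Hspa8 (415 ± 32.1 and 698 ± 201 CPM). Serotonin, dopamine and histamine signalling genes had a median of -0.27 (0.418, corrected -0.25), with 0 of 26 past the threshold adjusted over the list alone.

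Among markers of cell types and tissues, ependymal and tanycyte genes had a median of 0.07 (adjusted p 0.424, corrected -0.0145, so that its sign turned), with 5 of 21 higher and 3 lower adjusted over the list alone, Vim being at 30.1 ± 4.14 and 55.5 ± 18.1 CPM and Lhx2 at 20.7 ± 5.36 and 9.65 ± 1.53 CPM. Choroid plexus genes had a median of 0.33 (0.23, corrected 0.16), with 2 of 15 higher, 1 of them Prlr. Blood cell genes had the most negative median of all lists, -1.11 (0.0606, corrected -0.87), with 5 of 12 lower, the haemoglobin gene Hbb-bs being at 258 ± 90.1 and 110 ± 51.9 CPM. Endothelial and mural genes had a median of -0.22 (0.423, corrected -0.06), with 1 of 22 lower, the tight junction gene Cldn5 (55.1 ± 7.14 and 29.0 ± 5.41 CPM). Transcription factors of hypothalamic nuclei had a median of -0.27 (0.265, corrected -0.14, where camera's direction turned upward), with Sim1 higher and Nkx2-2 lower (18.1 ± 0.242 and 12.0 ± 1.02 CPM). Immature neuron genes had a median of -0.32 (0.341, corrected -0.17), with 1 of 25 lower, Tubb3 (722 ± 58.5 and 446 ± 56.5 CPM). No member passed adjusted over the list alone for the ageing brain (median 0.21, 0.279, corrected 0.08), replication-dependent histones (-0.49, 0.414, corrected -0.17) or meningeal and perivascular fibroblasts (-0.12, 0.985, corrected -0.04, where camera's direction turned upward).

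The first pattern weighed was the number of genes at an unadjusted p under 0.05, 6480 of 17390. A GC content and length bias between libraries is argued against as the whole cause, because 5745 genes were at that level after the correction, although fold changes followed GC content. The part it played cannot be read from these counts, since the correction also changes the spread within genotypes. In other splits it raised some counts (511 to 724 in the split that follows Xist) and lowered others (4179 to 3035 for WT 10, WT 11 and Kcnb1-NULL 14). A difference between the sexes, so far as the level of Xist marks it, is argued against as the whole cause. With Xist as a covariate, which ended 5 list calls, 6284 genes were at that level. The split that follows Xist (WT 10, WT 173 and Kcnb1-NULL 115 against the rest) gave 511. Each side of that split holds both genotypes, so their difference adds to its spread and 511 does not measure the sexes alone. A difference between the sexes can still have a part, since Xist was high in WT 11 alone of the WT libraries and in Kcnb1-NULL 14 and 15. An unspliced or nuclear RNA share stays open beside genotype, while age is given alike for both genotypes. Nuclear-retained RNAs separated the genotypes by their share of counts. After the GC correction their median fell from 0.61 to 0.18 and their camera call ended (adjusted p 0.173, or 0.19 without Xist). The mean share of the gene class TEC differed by 0.0276 percent of counts against a pooled SD of 0.0279, too near that bound to decide. That SD includes differences between the number series of the animals, within each of which Kcnb1-NULL was higher. Kcnb1-NULL 14 and 15 were at 0.0734% and 0.0861% against 0.0527% and 0.0622% in WT 10 and 11. Kcnb1-NULL 115 was at 0.1343% against 0.0961% in WT 173. The lncRNA share separated the genotypes (0.954% to 1.35% in WT, 1.42% to 2.13% in Kcnb1-NULL). The sense intronic share did not (0.047% in Kcnb1-NULL 15, 0.0473% in WT 173). Of 10 splits of the 6 libraries, 1, the real one, gave as many genes, the highest other being 4179 (WT 10, WT 11 and Kcnb1-NULL 14 against the rest), and 10 splits are too few for a share under 0.05. For genes past an adjusted p of 0.05 in edgeR the real count was 0 (4023 in DESeq2). All 10 splits therefore had to give as many, and this count decides nothing. The highest other was 5 (Xist, Ddx3y, Eif2s3y, Kdm5d and, outside the naming rule, Oacyl). For lists 8 of the 10 splits, the real one among them, gave at least the real 12. The number of list calls therefore did not set the genotypes apart from other splits. Those splits hold the genotypes unequally on their sides, so they are not free of the genotype difference. A number of calls also leaves out how strong each call is. The highest other, 29 lists, came from the split that follows Xist, and the cause of that was not tested.

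The second pattern was the lower level of striatal and of cortical, hippocampal and amygdalar markers, with a median log2 fold change of -0.82 over 36 genes. Without WT 173 the median was -0.54 for the striatal and -0.40 for the cortical list. A GC content and length bias is argued against by the median after the correction, -0.81. Different amounts of cortical and striatal tissue between dissections could contribute. Within genotypes the corrected members moved together with a mean pairwise correlation of 0.452, above the highest of 1000 random lists (0.209). Those random lists were matched on mean expression only. WT 173 had the highest share of counts for both marker lists (0.1106% striatal, 0.1927% cortical). The correlation was not computed without WT 173, so 1 library may have produced much of it. Camera's estimated correlation, before the correction, was also high for oxidative phosphorylation genes (0.727, against 0.458 for the cortical and 0.442 for the striatal list). Moving together is therefore not particular to tissue amounts. Of the cortical and striatal markers 19 of 20 and 15 of 16 had a mean CPM of at least 1, and 1 and 4 are in another list. Tissue carried along would give such levels too, so they cannot show whether the hypothalamus itself expresses these genes. A genotype effect in hypothalamic cells was not tested and stays open. The median was 0.824 in size in the real split and at most 0.623 in the others, so 1 of 10 splits was as large, too few to exclude chance.

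The third pattern was the 72.3-fold range of Pomc over the libraries. Different amounts of pituitary tissue between samples may account for it, as Pomc ranked with the summed pituitary hormone genes Prl, Gh and Cga in all 6 libraries (Spearman's rho 1, exact permutation p = 0.00278, and Pearson's r of log2 values 0.908, exact permutation p = 0.00139, the 1 relation tested). Without the 2 libraries farthest from the median, r was 0.837 over 4. The libraries with high Xist (WT 11, Kcnb1-NULL 14 and Kcnb1-NULL 15) were also the highest in Pomc, at 675 CPM or more. The others were at 104 CPM or less. The summed hormone genes split in the same way, at 705 CPM or more against 350 CPM or less. The relation therefore cannot separate amounts of pituitary tissue from a difference between the sexes. Different amounts of arcuate tissue are argued against, because Agrp, expressed in the same nucleus, spanned 0.167 of the log2 range of Pomc (1.03 against 6.18). No biological explanation was tested, and the hormone genes did not set the level alone, since WT 11 and Kcnb1-NULL 14 had 1548 and 1589 CPM of Pomc with 929 and 15285 CPM of those genes.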
